A study of Mus musculus with 15 samples.

How the data were processed

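RNA was sequenced from 15 libraries of mouse hematopoietic stem cells, in 4 groups: untreated (n = 4), 5-FU day 4 (n = 4), cultured control (n = 3) and cultured nifedipine (n = 4). Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, 100 cells were sorted per sample, complementary DNA was made by a modified published method, and libraries were prepared with a Nextera XT kit, which does not mark strand. Per the series design text, sequencing was done on a NextSeq instrument. The aligner, the counting program and its settings are not given in the sources used here. The genome build is mm10, per the submitters' processing notes.

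Per the file headers, the deposited table of each library gives a chromosome, a region, a feature name, the total exon reads (whole-number counts) and an RPKM value, which is the count scaled by exon length and by a read total, as the authors computed it. The deposited counts were used for all tests. The RPKM values served only to recover exon lengths and the read total behind them. For a gene without introns the exon length is the span of the gene, so its count, RPKM value and span give that total, which was used as an alternative library size. Each table holds 48737 features. Features of 1 gene listed more than once on alternate scaffolds were added up, which gave 46123 genes. This joined 4537 copies of 1923 genes with 4.66% to 4.94% of the exon reads, and 31 copies stayed split. Coordinates are those of the files, changed to start at 1. A RefSeq gene table of the GRCm38.p6 assembly was used for gene types, and 41488 genes matched it by symbol. All 37 mitochondrial features had 0 reads in every library, and 67 of 11908 non-coding RNA genes had any read, so neither class was analysed here. Without strand in the library, reads of a gene and of an antisense gene cannot be told apart, and reads of near-identical copies may be split between them.

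Exon reads per library lay between 6171730 and 26673045. Within each group, no library was close to a copy of another. Each comparison was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr at its defaults, a quasi-likelihood F test, group as the only term and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p of 0.05 or less. The common biological coefficient of variation was 0.202 in the 5-FU comparison and 0.13 in the nifedipine comparison. CPM values in the text are counts scaled to the exon reads of the library after TMM, and log2 fold changes are treated minus reference. A fold against a group at 0 reads was taken against a floor of 3 reads over the group. Ratios with 1 to 3 reads in a group have a 95% exact counting interval.

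Before the data were examined, 36 gene lists were written, on stem cell identity, quiescence, cell cycle, metabolism, mitochondria, calcium, adenosine, p53, interferon, stress, growth and markers of other blood and marrow cells. The list of genes encoded by mitochondrial DNA was left out, since those features have 0 reads. Lists with 5 or more tested members were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The counts given as adjusted over the list alone adjust the p-values of the members of that list only.

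Genes were named by a rule written before the data were examined. In each comparison it took the 10 called genes with the largest log2 fold change in each direction among those whose groups did not overlap, with a symbol that is not a predicted or clone name and a mean of at least 10 CPM in the higher group. It also took the 4 members with the smallest p of each list that passed, and always Cdkn1c, Cdkn1a, Mki67, Ccnd1, Ccnd2, Myc, Hlf, Mecom, Procr, Fgd5, Slamf1, Kit, Cacna1c, Cacna1d, Cacna1s, Mcu, Ppargc1a and Txnip. A gene of the first 2 parts in 1 comparison could be given in the other. List members named to spell out a count of 5 or fewer, Gfi1, Gbp4, Gzmb, Cacnb2, Mycn with nifedipine and the genes of the closing part were chosen after their values were seen. Some genes that the rule or a count would name are not reported here.

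The nifedipine change was set against the 5-FU change by Pearson and Spearman correlation across genes, with an exact permutation test over all 35 assignments of the cultured libraries, and by camera on the genes called after 5-FU. The edgeR fit and camera with its preset correlation were tested on simulated data. These held 200 changed genes, far fewer than were called in the real libraries. The correlation between comparisons, fry, the estimated correlation and the alternative scalings and corrections were not simulated. For the 5-FU comparison, 83% of the genes changed 2-fold and 58% of those changed 1.5-fold were called, with 6 false calls among 147, on 13384 genes. For the nifedipine comparison these were 97%, 77% and 9 among 183, on 12807 genes. Of the unchanged lists, 0 of 32 and 0 of 31 were called. Genes were simulated independently of each other, so this does not measure false list calls among correlated genes. Over other splits of the real libraries, up to 22 lists were called in the 5-FU comparison and 18 in the nifedipine comparison.

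Alternatives planned before the data were examined were DESeq2 size factors, no filter, a filter of 10 CPM, the replicate number as a block, DESeq2 1.42.0, limma-voom with sample weights, all 4 groups in 1 fit, a 2-fold minimum and leaving out each library in turn. A planned change of pseudocount did not apply, since the files hold counts. Chosen after seeing the data were features as deposited, the RPKM read total as library size, a correction for a trend with exon length and GC content in each library, the 5-FU comparison without untreated 3 and 5-FU 4, and leaving out each untreated or 5-FU library for the last comparison. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.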

Results

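Hematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and give rise to all blood lineages, were profiled by RNA sequencing in 15 libraries made from 100 sorted cells each, from wild-type C57BL/6 mice. The first experiment took freshly sorted HSCs of untreated mice (n = 4) and of mice at day 4 after 5-fluorouracil (5-FU, n = 4), a pyrimidine analog that kills dividing blood cells and is used to drive the surviving HSCs into division. The second experiment took cultured HSCs without (n = 3) or with (n = 4) nifedipine, a dihydropyridine that blocks L-type voltage-gated calcium channels, sorted from cells that had divided at most 3 times. The dose of the drugs and the length of the culture are not given in the sources used here. Exon reads per library ranged from 6171730 to 16685285 in untreated HSCs, from 9775640 to 17397392 after 5-FU, from 20145079 to 26673045 in cultured control HSCs and from 17582453 to 22372771 with nifedipine. Between 14206 and 15845 genes had at least 1 read in a library. The labels do not state that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Intervals and floors given for genes near 0 reads cover counting error only, since the reads carry no molecular identifiers.

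The first comparison asked which genes differ between HSCs at rest and HSCs driven into division by 5-FU. At day 4 after 5-FU, genes of cell division and energy production were higher, and genes of stem cell identity and of the immediate early response were lower. These are list calls of camera with its preset correlation, and with an estimated correlation their adjusted p was 0.35 or 0.354. Mki67, the gene of the proliferation marker Ki-67 (mm10 chromosome 7, 135689788 to 135716409), rose from 162 ± 129 to 1336 ± 80.8 CPM (counts scaled to library size; mean ± SD, n = 4 each; log2 fold change 3.03 ± 0.45 SE, adjusted p = 0.000301). Hlf, a transcription factor of long-term HSCs (chromosome 11, 90336535 to 90390917), fell from 1753 ± 104 to 976 ± 67.7 CPM (adjusted p = 3.88e-06). Gem, a small GTPase that binds the beta subunits of voltage-gated calcium channels (chromosome 4, 11704447 to 11714993), rose from 30.2 ± 8.79 to 967 ± 104 CPM (log2 fold change 4.97 ± 0.19 SE, adjusted p = 9.94e-07). Btg2, an antiproliferative immediate early gene (chromosome 1, 134074865 to 134079155), fell from 209 ± 60.8 to 11.2 ± 4.10 CPM (log2 fold change -4.19 ± 0.27 SE, adjusted p = 2.92e-06). Other large falls were in Shisa9, Epb42, Zc3h6, Pbld1 and Fn3k, at -3.85, -2.96, -2.92, -2.81 and -2.78.

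The mitosis list rose as a whole, with all 38 measured members higher (38 adjusted over the list alone) and a median log2 fold change of 3.10 (camera adjusted p = 1.81e-12, 0.354 with an estimated correlation). Ube2c, which marks mitotic proteins for degradation, rose by 4.84, the kinesin Kif2c by 4.06, cyclin B2 (Ccnb2) by 3.91 and the mitotic kinase Aurkb by 3.72 on the log2 scale. Nuf2, Birc5, Kif20a, Cdc25c and Ccna2 rose by 3.80, 3.69, 3.68, 3.61 and 3.58. Cdk1, the kinase that starts mitosis, rose by 2.98, and its partner Ccnb1 by 3.52. All 42 genes of DNA replication rose (42 adjusted over the list alone; median 1.48, adjusted p = 1.27e-16), among them Rrm1 at 1.89 and the helicase subunit Mcm2 at 1.72. Of 44 replication-dependent histone genes, 32 rose and 0 fell (36 and 0 adjusted over the list alone; median 1.94, adjusted p = 3.49e-08), with Hist2h2bb up by 2.33. Among 16 G1 cyclins, cyclin-dependent kinases and E2F factors, 13 rose and 1, Ccnd2, fell (13 and 1 adjusted over the list alone). The median was 1.00 (camera adjusted p = 1.47e-05). There were 0 falls without untreated 2 and 2 without untreated 4. Ccnd1, a G1 cyclin (chromosome 7, 144929931 to 144939937), rose from 45.2 ± 10.9 to 231 ± 22.4 CPM. The adjusted p was 0.35 with an estimated correlation for the replication, histone and G1 lists.

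Mitotic transcripts were spread unevenly among the untreated libraries. Untreated 3 had a mean of 4.38 log2 CPM over the mitosis list, against 1.66 to 3.19 in the other untreated libraries and 6.30 to 6.58 after 5-FU, and on the first principal component it stood at -9.0 against -46.9 to -66.5. Without untreated 3 the list median was 4.00, Ube2c rose by 6.20, Kif2c by 5.29, Ccnb2 by 4.68, Nuf2 by 4.63, Aurkb by 4.99 and Birc5 by 4.45. Likewise Kif20a rose by 4.51, Cdc25c by 6.07, Ccna2 by 4.30 and Mki67 by 3.69. With limma-voom and all libraries, Kif2c stood at 5.47, Ccnb2 at 5.35 and Cdc25c at 6.14.

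Nuclear-encoded genes of oxidative phosphorylation rose in 70 of 78 cases, and Cox7a2l and Atp5s fell, which made 2 (71 and 3 adjusted over the list alone; median 0.74, adjusted p = 3.91e-17). The ATP synthase subunit Atp5b rose by 1.01, Ndufa4 by 1.11 and Cox5a by 1.39. Of 23 genes of the tricarboxylic acid cycle, 21 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.57, adjusted p = 1.24e-08), with Mdh2 up by 1.06 and Idh3a by 1.34. Mitochondrial biogenesis and dynamics rose in 24 of 36 genes (25 adjusted over the list alone; median 0.40, adjusted p = 1.53e-05), including the chaperone Hspd1 at 1.15 and the ADP/ATP carrier Slc25a5 at 1.47. The 3 that fell (3 adjusted over the list alone) were Ppargc1a, a coactivator that promotes mitochondrial biogenesis, Tfb2m and Polg2. Glycolysis genes rose in 15 of 26 cases (16 adjusted over the list alone; median 0.28, adjusted p = 0.0105), with Pkm up by 1.01, Ldha by 1.21 and Pgk1 by 1.36, while Aldoc, Ldhb, Pdk1 and Pdk2 fell. The 32 measured MYC targets and ribosome biogenesis genes gave 30 rises and 0 falls (30 and 0 adjusted over the list alone; median 0.77, adjusted p = 3.24e-10), with Npm1 up by 1.04 and Cad by 1.34. Myc itself stood at 76.6 ± 13.1 and 77.7 ± 9.29 CPM (log2 difference 0.02, adjusted p = 0.896). Each of these lists had an adjusted p of 0.35 with an estimated correlation.

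Exon length and GC content moved these values. Oxidative phosphorylation genes have a median exon length of 768 bases against 3498 over all tested genes, and log2 fold change fell with length across genes, which are not independent replicates (Spearman rho -0.205). In a fit corrected for length and GC content the median of the list was 0.40, with 56 genes higher and 6 lower. The 81 ribosomal protein genes gave 19 rises and 17 falls (19 and 16 adjusted over the list alone; median 0.01, adjusted p = 0.857), a median of 0.21 with the read total behind the RPKM values as library size (46 rises and 1 fall, adjusted p = 0.0153) and -0.32 in the corrected fit (6 rises and 62 falls, adjusted p = 1.88e-10).

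Genes of HSC identity fell in 29 of 38 cases and rose in 0 (29 and 1 adjusted over the list alone; median -0.47, adjusted p = 1.9e-06, and adjusted p = 0.35 with an estimated correlation). Mllt3 fell by 0.67, the receptor Kit by 0.61 and Procr, the endothelial protein C receptor used to sort HSCs, by 0.42. With the RPKM read total as library size, 15 fell and 3 rose, Procr no longer passed (adjusted p = 0.0967), and Fgd5 changed from -0.19 (adjusted p = 0.0298) to 0.008 (adjusted p = 0.935). Fgd5 also lost its call without untreated 4 (adjusted p = 0.0837), without 5-FU 1 (0.0533), with all 4 groups in 1 fit (0.102), in the length and GC corrected fit (0.479) and without untreated 3 and 5-FU 4 (0.0822). Mecom was at 646 ± 69.0 and 735 ± 48.1 CPM (log2 difference 0.19, adjusted p = 0.068) and passed without 5-FU 4 (0.0324), without untreated 3 and 5-FU 4 (0.0257), with DESeq2 (0.0464), limma-voom (0.0333), the RPKM read total (0.00223) and the length and GC correction (0.00581). In this list 1 gene rose without untreated 3, untreated 4 or 5-FU 4. Slamf1 was at 37.6 ± 8.52 and 38.0 ± 1.49 CPM (adjusted p = 0.965).

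Immediate early genes, which respond within minutes to stimulation or handling, fell in 19 of 27 cases (19 adjusted over the list alone; median -1.42, adjusted p = 4.62e-06, and adjusted p = 0.35 with an estimated correlation). Egr1 fell by 2.63, Dusp2 by 2.17, Ier2 by 2.09 and Egr3 by 2.75 on the log2 scale. The heat shock gene Hsph1 alone rose (1 adjusted over the list alone). Inflammation and NF-kB genes fell in 14 of 20 cases (15 adjusted over the list alone; median -0.72, adjusted p = 0.00146, and adjusted p = 0.354 with an estimated correlation), with the chemokine Ccl4 at -2.89 and the inhibitor Nfkbia at -1.33. Nfkb1 and Tnf rose, which made 2 (2 adjusted over the list alone; 1 without untreated 1 or 5-FU 4). Cholesterol synthesis and uptake genes fell in 21 of 24 cases and rose in 0 (21 and 0 adjusted over the list alone; median -0.77, adjusted p = 5.31e-06, and adjusted p = 0.35 with an estimated correlation). Insig1 fell by 1.68 and Msmo1 by 1.60, and without untreated 1 there was 1 rise.

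Of 23 quiescence regulators, 13 fell and 5 rose (14 and 5 adjusted over the list alone; median -0.47), and the list did not pass (adjusted p = 0.0551, 0.379 with an estimated correlation). It passed without untreated 1 (0.0466), without 5-FU 3 (0.0462), without untreated 3 and 5-FU 4 (0.0458), with no filter (0.0453), at 10 CPM (0.0331), with features as deposited (0.0402) and with the RPKM read total (0.0145). Txnip, a thioredoxin inhibitor, fell from 1273 ± 360 to 589 ± 68.5 CPM, and the cell cycle inhibitor Cdkn1c by 0.49. The rises were in Cdkn1a, Cdkn2c, Trp53, Rbl1 and Fbxw7, with 3 rises without untreated 2, 5-FU 1, 5-FU 2 or 5-FU 3, and 8 rises and 11 falls with the RPKM read total. Cdkn1a, the inhibitor p21, was at 6.93 ± 5.23 and 16.6 ± 2.10 CPM (log2 fold change 1.24, adjusted p = 0.0406). That call was lost without untreated 1 (0.0662), untreated 2 (0.0770), 5-FU 1 (0.0620), 5-FU 2 (0.0780), 5-FU 3 (0.0882) or 5-FU 4 (0.0760), without untreated 3 and 5-FU 4 (0.0714), and in the length and GC corrected fit (0.0547). Ccnd2 fell by 0.12 (adjusted p = 0.0227), with 0.0673 without untreated 2 and 0.864 in the corrected fit, and its value turned to 0.08 with the RPKM read total (adjusted p = 0.168).

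Genes of L-type calcium channels, the target of nifedipine, were near the lower end of expression. Cacna1c was at 8.02 ± 1.61 and 5.73 ± 1.78 CPM (log2 difference -0.47, adjusted p = 0.16; 0.0441 without untreated 3 and 5-FU 4), Cacna1d at 10.7 ± 1.72 and 9.80 ± 2.52 CPM (adjusted p = 0.655), and Cacna1s had 2 reads over all 8 libraries. Among 10 voltage-gated channel subunits, 4 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.61, adjusted p = 0.0296, and adjusted p = 0.35 with an estimated correlation). Those were Cacna1a, Cacnb1, Cacna1b and Cacna2d4, at -0.99, -0.69, -2.35 and -0.99. Like the endothelial and stromal markers, this list was lowest among untreated libraries in untreated 3 (mean 2.501 log2 CPM against 2.93 to 3.12). It was highest among 5-FU libraries in 5-FU 4 (2.41 against 1.77 to 2.24). Without both libraries 6 fell (camera adjusted p = 0.0106). Leaving out that pair kept untreated libraries high and 5-FU libraries low in those markers, so it cannot separate this fall from theirs. The list lost its call with no filter (0.11) and in the corrected fit (0.0739). Cacna1b stood at -1.71 without untreated 2, Cacnb1 lost its call with the RPKM read total (0.0557), and Cacna2d4 lost its call there (0.0579) and without untreated 2 (0.0688), 5-FU 2 (0.0517) or 5-FU 3 (0.0630). Calcium transport and sensing genes gave 19 rises and 7 falls of 49 (19 and 8 adjusted over the list alone; median 0.12, adjusted p = 0.0926, 0.354 with an estimated correlation), and this list passed with no filter (0.0422) and in the corrected fit (0.0403), with 26 rises and 4 falls with the RPKM read total. Mcu, the mitochondrial calcium uniporter, rose by 0.79, and Ppargc1a fell by 0.87.

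Smaller shifts were close to the threshold. Fatty acid oxidation genes rose in 12 of 26 cases, while Acadm, Acad10 and Crat fell (12 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.0458). Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 0.69. The call was lost without untreated 2 (0.0597), 5-FU 1 (0.0623) or 5-FU 2 (0.0506), at 10 CPM (0.0956), with features as deposited (0.0701) and in the corrected fit (0.202), and the RPKM read total gave 16 rises and 1 fall. Integrated stress and unfolded protein response genes rose in 15 of 25 cases (15 adjusted over the list alone; median 0.48, adjusted p = 0.0466), led by the serine synthesis genes Psat1 at 1.52 and Phgdh at 1.11, whereas Atf4, Ddit3, Trib3, Vldlr and Dnajb9 fell (5 adjusted over the list alone). This call was lost without untreated 1 (0.0554), untreated 2 (0.0797), untreated 4 (0.0522) or 5-FU 1 (0.0623), with the RPKM read total (0.157) and in the corrected fit (0.0611). The adjusted p was 0.35 with an estimated correlation for both lists.

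Mitophagy, autophagy and lysosome genes fell in 17 of 33 cases, with rises in Atg3, Lamp1, Ctsz and Atp6v1h (17 and 4 adjusted over the list alone; adjusted p = 0.0466, and adjusted p = 0.35 with an estimated correlation), and the median of -0.18 turned to 0.02 with the RPKM read total, where 10 rose and 10 fell. The autophagy kinase Ulk1 fell by 0.97 and Pink1, which marks damaged mitochondria, by 1.14. The call was lost without untreated 1 (0.0625), untreated 2 (0.0603), 5-FU 1 (0.0623), 5-FU 2 (0.0667) or 5-FU 4 (0.0696), without untreated 3 and 5-FU 4 (0.0530), with features as deposited (0.0577) and with the RPKM read total (0.0928). Cytokine receptor and adhesion genes fell in 12 of 25 cases, with rises in Tgfbr1, Itgb1 and Cd44 (12 and 4 adjusted over the list alone; median -0.21, adjusted p = 0.0466, and adjusted p = 0.387 with an estimated correlation). Il6ra fell by 1.27 and Csf2ra by 0.97. This list too was lowest in untreated 3 (mean 6.23 log2 CPM against 6.42 to 6.53 in the other untreated libraries). It was highest in 5-FU 4 (6.20 against 5.99 to 6.10), like the endothelial and stromal markers. Without both libraries 13 fell (camera adjusted p = 0.0150), which cannot separate this fall from that of those markers. The call of cytokine receptor and adhesion genes was lost without untreated 4 (0.0585), 5-FU 1 (0.0665), 5-FU 2 (0.0714) or 5-FU 3 (0.0525). It was also lost with the RPKM read total (0.0527, with 4 rises and 8 falls) and in the corrected fit (0.0739).

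Lists of p53 targets, interferon response, adenosine signalling and apoptosis did not pass after 5-FU. Of 31 p53 targets, 15 rose and 8 fell (15 and 8 adjusted over the list alone; median 0.36, adjusted p = 0.222). Interferon response genes gave 6 rises and 10 falls of 38 (6 and 10 adjusted over the list alone; adjusted p = 0.372), with a median of -0.07 that turned to 0.12 with the RPKM read total (11 rises and 7 falls; 1 and 10 in the corrected fit). Adenosine and nucleotide signalling gave 10 falls of 20 and rises in Ada, Adk, Slc29a1 and P2rx7 (10 and 5 adjusted over the list alone; median -0.24, adjusted p = 0.257), and 6 rises and 8 falls with the RPKM read total. Apoptosis regulators gave 8 rises of 19 and falls in Mcl1, Bcl2l11, Bmf, Birc2 and Birc3 (8 and 6 adjusted over the list alone; median 0.10, mean -0.05, test direction up, adjusted p = 0.821).

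Markers of other marrow cells differed between libraries of the same group. The 17 endothelial and stromal markers had a mean of 0.85 log2 CPM in untreated 3 against 4.42 to 4.81 in the other untreated libraries, and of 3.37 in 5-FU 4 against 0.50 to 1.32 in the other 5-FU libraries. In that list 6 genes fell and 0 rose (4 and 0 adjusted over the list alone; median -2.44, adjusted p = 0.0559, 0.526 with an estimated correlation). Kdr, a vascular endothelial growth factor receptor, was among them at -3.32, with -2.22 without untreated 1 and -2.58 with the replicate number as a block. Without untreated 1 or 5-FU 1, 2 genes fell. The list passed with no filter (0.0453) and with the RPKM read total (0.00527), with 9 falls without untreated 3 (adjusted p = 0.00952), 10 without 5-FU 4 (0.0209) and 14 without both (0.000425; median -3.81). Without both libraries, 21 lists passed in place of 18, the mitosis list kept 38 rises of 38 and HSC identity gave 26 falls and 2 rises of 38. Every untreated library left was then higher in the endothelial and stromal markers than every 5-FU library left. Leaving out the pair is therefore no check against an effect of these markers. Macrophage markers had the same order, with 1.79 log2 CPM in untreated 3 against 3.51 to 4.25 and 3.55 in 5-FU 4 against 3.02 to 3.36, as had granulocyte and monocyte progenitor markers, with 2.495 against 2.99 to 3.71 and 3.31 against 2.70 to 2.80. B cell markers, with 3.10 against 3.12 to 4.30 and 3.27 against 1.83 to 2.21, lymphoid progenitor markers, with 4.16 against 4.28 to 4.54 and 4.19 against 4.13 to 4.16, and adenosine signalling, with 4.66 against 4.66 to 4.79 and 4.64 against 4.48 to 4.59, did so too.

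Erythroid markers averaged 5.08 and 5.18 log2 CPM in untreated 2 and 4, against 3.45 and 2.90 in untreated 1 and 3, but without the globins the 8 others averaged 3.64 and 3.73 against 3.55 and 3.16. Of 11 erythroid markers, Epor, Car2, Tfrc and Aqp1 rose while Hba-a2 and Hbb-bs fell, which made 4 and 2 (4 and 2 adjusted over the list alone; median -0.39, mean -1.84, test direction up, adjusted p = 0.857). The falls were 6 without untreated 3 (3 rises of 15 members, median -0.99) or 5-FU 3 (4 rises of 14) and 5 without 5-FU 1 (3 rises), 5-FU 2 (4 rises) or 5-FU 4 (3 rises), each with 15 members. Hba-a2 had 5506 reads in untreated HSCs and 0 after 5-FU, at least 2020-fold lower with a floor of 3 reads over the group and at least 906-fold lower without untreated 4. It stood at 278 and 252 CPM in untreated 2 and 4 and 1.40 and 0.662 CPM in untreated 1 and 3. Reads can be split among its near-identical copies, so its level is uncertain, and limma-voom did not call it (adjusted p = 0.426). B cell markers gave 4 falls of 6, in Cd74, H2-Aa, H2-Ab1 and Cd22 (4 adjusted over the list alone; median -1.12, adjusted p = 0.0662), and 2 without untreated 2, untreated 4, 5-FU 2 or 5-FU 3. That list passed without untreated 1 (0.0369), without 5-FU 4 (0.0367), without untreated 3 and 5-FU 4 (0.0359), with the RPKM read total (0.0162) and in the corrected fit (0.0457). Macrophage markers gave 2 falls of 17, in Apoe and Lyz2 (1 adjusted over the list alone; median -0.27, adjusted p = 0.727), and passed without untreated 3 and 5-FU 4 (5 falls, median -0.86, adjusted p = 0.0301). There were 6 falls without untreated 3 (median -0.65, adjusted p = 0.0524), 4 without 5-FU 2 and 1 without untreated 1 (median 0.20), untreated 4, 5-FU 1 or 5-FU 4 (median -0.58).

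Granulocyte and monocyte progenitor markers gave 4 falls of 12, in Prtn3, Csf3r, Gstm1 and Plac8 (4 adjusted over the list alone; median -0.57, adjusted p = 0.186). Megakaryocyte and platelet markers gave 7 falls of 20 and rises in Selp, F2r and Cd9 (7 and 3 adjusted over the list alone; median -0.49, adjusted p = 0.192), and 5 rises and 6 falls with the RPKM read total. Lymphoid progenitor markers gave 3 rises of 11, Il12a and Lsp1 among them, and falls in Flt3, Satb1 and Bcl11a (3 and 3 adjusted over the list alone; adjusted p = 0.518), with a median of -0.19 that turned to 0.003 with the RPKM read total and 1 rise without 5-FU 4. Too few members were measured to test mature neutrophil markers (0 calls of 2), T and NK cell markers (Cd247 and Klrb1c lower, 2 of 4) and mast cell and basophil markers (Slc18a2 and Mitf lower, 2 of 3). The counts for these 3 lists were the same adjusted over the list alone. Without untreated 4 a neutrophil marker fell (1 of 3), and T and NK cell markers gave 1 fall on leaving out any library other than untreated 4 or 5-FU 3.

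Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6765 of 13384, of which 3580 were higher and 3185 lower (52.9% higher). The libraries of the 2 groups did not overlap for 6331 genes (47.3%, against 2.86% by chance). Scaling decides the balance: with the read total behind the RPKM values as library size, all log2 fold changes moved up by a median of 0.198 and 73.6% of 6993 calls were higher, so the directions here are relative to the typical gene. Exon reads made up 25.5% ± 0.551 of that total in untreated HSCs and 31.0% ± 0.877 after 5-FU (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). Of 32 lists tested, 18 passed with camera's preset correlation, 11 up and 7 down, and 0 with an estimated correlation.

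**Figure D1:**
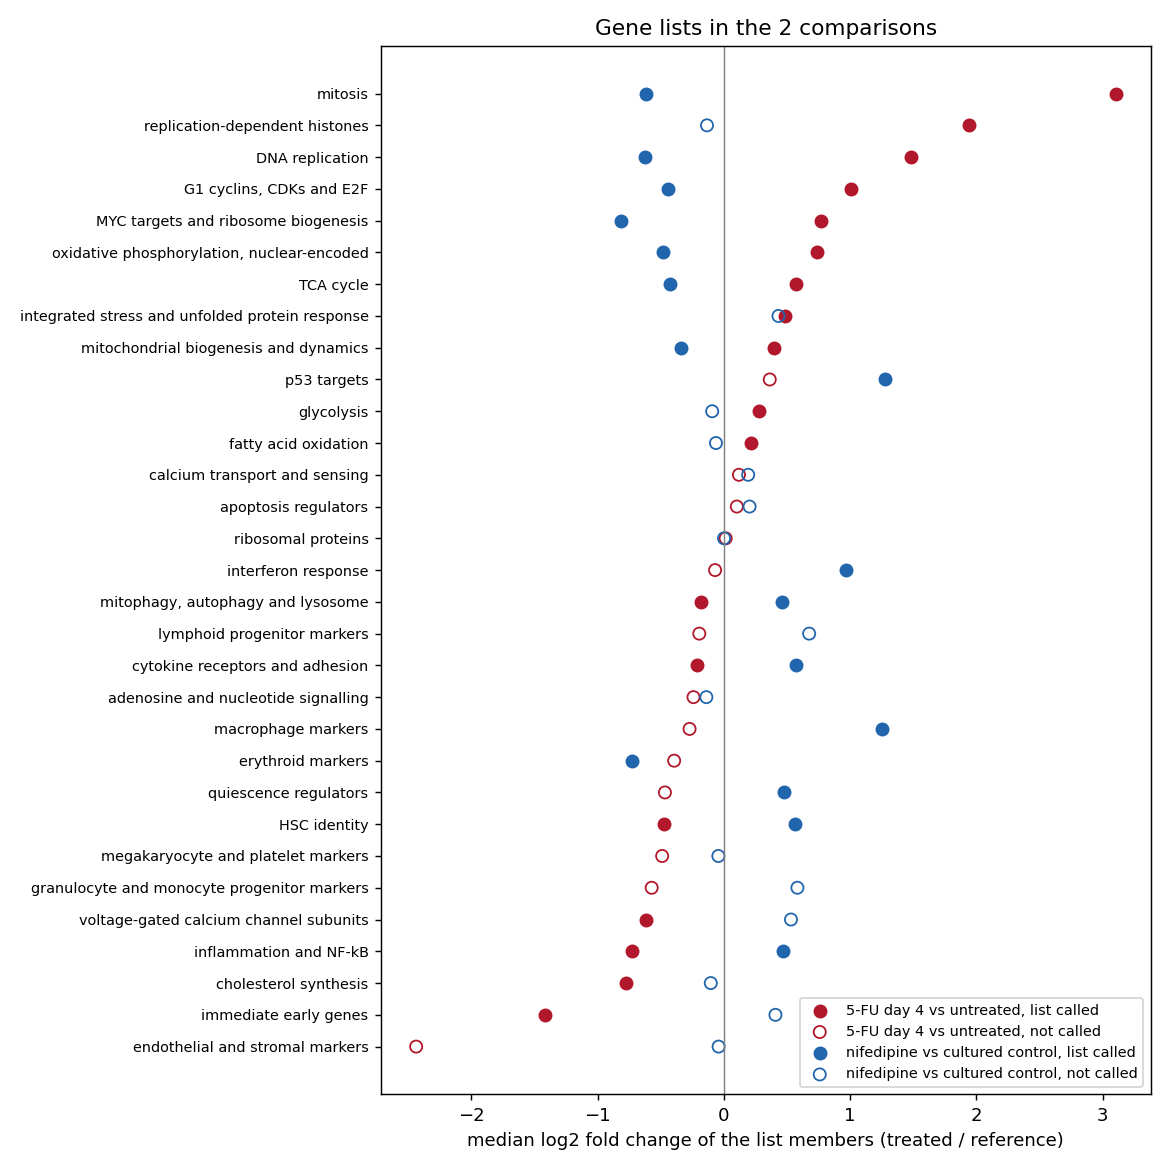
Median log2 fold change of the members of each gene list (x axis) for the 31 lists tested in both comparisons (y axis). Red marks 5-FU against untreated HSCs and blue nifedipine against cultured control, with filled points for lists that passed the camera test. Mitosis stands at 3.10 after 5-FU and -0.62 with nifedipine, and oxidative phosphorylation at 0.74 and -0.48.

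**Figure D2:**
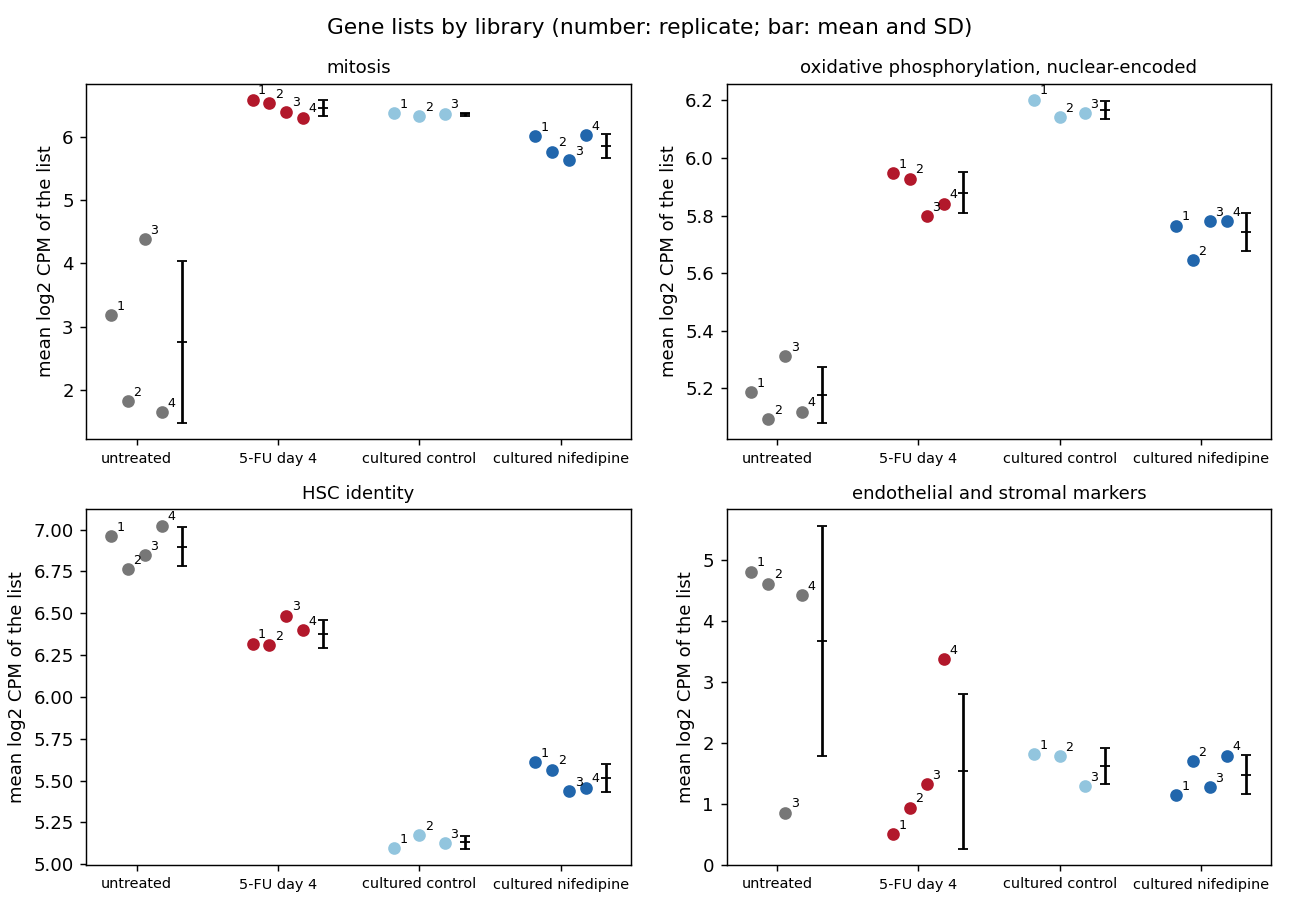
Mean log2 CPM of 4 lists in each of the 15 libraries, numbered by replicate, with bars for the group mean and SD. Means are over the members tested in each experiment (17 and 9 for endothelial and stromal markers), with scaling fitted in each. Levels are therefore not comparable between the experiments. Untreated 3 lies at 4.38 for mitosis and 0.85 for endothelial and stromal markers, apart from the other untreated libraries.

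The second comparison asked how nifedipine, a blocker of L-type calcium channels, changes the transcriptome of HSCs in culture. With nifedipine, targets of p53, interferon response genes, lysosomal genes and several HSC identity genes were higher, and genes of ribosome biogenesis, DNA replication and mitochondrial energy production were lower. These calls too rest on the preset correlation, and with an estimated correlation the adjusted p was 0.0905 for p53 targets and ribosome biogenesis, 0.127 for interferon, 0.117 for autophagy and lysosome and 0.17 for HSC identity, replication and oxidative phosphorylation. Hlf rose from 196 ± 15.1 CPM in control culture (n = 3) to 529 ± 45.8 with nifedipine (n = 4; log2 fold change 1.43 ± 0.07 SE, adjusted p = 1.11e-10). Cdkn1a (chromosome 17, 29090979 to 29100722) rose from 11.7 ± 2.56 to 60.5 ± 5.48 CPM, and Txnip (chromosome 3, 96557957 to 96561857) from 79.1 ± 1.62 to 245 ± 14.2 CPM. Mki67 fell from 1411 ± 25.3 to 769 ± 36.5 CPM (log2 fold change -0.88 ± 0.05 SE, adjusted p = 3.3e-10).

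Aldh1l2, a mitochondrial enzyme of folate metabolism (chromosome 10, 83487447 to 83534151), rose from 1.59 ± 0.0155 to 73.8 ± 9.70 CPM (log2 fold change 5.53 ± 0.15 SE, adjusted p = 5.65e-14). Hmox1, the heme-degrading oxygenase (chromosome 8, 75093618 to 75100593), rose from 3.27 ± 0.212 to 52.0 ± 4.41 CPM, and Slc40a1, the iron exporter ferroportin, by 4.30 on the log2 scale. The amino acid transporter Slc7a3 rose by 4.45, the pseudokinase Trib3 by 3.71, Chac1, which degrades glutathione, by 3.71, Sulf2 by 3.93, Ddit4l by 4.49 and Sel1l3 by 3.56. Ddit4l stood at 5.15 without cultured control 3 and Sel1l3 at 4.17 without cultured control 2. Ugt1a6b rose by 4.37 (3.72 without cultured control 1, 6.90 without cultured control 3, 6.17 with limma-voom). It shares exons with neighbouring Ugt1a genes, so which of them rose is uncertain. Falls included the receptor tyrosine phosphatase Ptprg (chromosome 14, 11553553 to 12242040) at -4.15 (-4.90 without nifedipine 3), the growth factor Fgf3 at -4.11 and the cation transporter Slc22a3 at -3.01. Podxl, a sialomucin of the cell surface (chromosome 6, 31519493 to 31563937), fell from 373 ± 31.0 to 51.4 ± 7.43 CPM. Clca3a1 stood at -2.98 (-4.11 without nifedipine 1), Mfsd2b at -2.87, Myom1 at -2.52, the integrin Itga2b at -2.50, the cholesterol exporter Abca1 at -2.47 and Sdpr at -2.46.

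Genes of HSC identity rose in 21 of 38 cases and fell in 8 (21 and 8 adjusted over the list alone; median 0.56, adjusted p = 0.00821, and adjusted p = 0.17 with an estimated correlation). Procr rose by 1.99, Ly6a, which encodes Sca-1, by 2.15, Vldlr by 2.90, Mecom by 0.83, Kit by 0.79 and Fgd5 by 0.57. Vldlr is also in the integrated stress list and in the list of ATF4 targets below, so its rise is not particular to HSC identity. Slamf1, the surface marker CD150, fell by 1.02. Of 23 quiescence regulators, 14 rose (14 adjusted over the list alone; median 0.47, adjusted p = 0.00247, and adjusted p = 0.156 with an estimated correlation), among them the transcription factors Foxo3 at 0.89 and Foxo1 at 1.12. The 3 that fell (3 adjusted over the list alone) were Cdkn1c, Cited2 and Trp53, with 1 fall without cultured control 3 and 1 with the RPKM read total. Cdkn1c fell by 0.60 (adjusted p = 0.0279), and lost that call without cultured control 1 (0.0740), cultured control 3 (0.0756), nifedipine 1 (0.0545) or nifedipine 4 (0.0530) and with the RPKM read total (0.0588). Gfi1, a repressor that restrains HSC division, had 0 reads in cultured control and 483 with nifedipine, at least 134-fold higher (81.2-fold without cultured control 1, since the floor is then over fewer reads).

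Of 33 measured p53 targets, 29 rose and 0 fell (29 and 0 adjusted over the list alone; median 1.28, adjusted p = 8.57e-11, and adjusted p = 0.0905 with an estimated correlation). Zmat3 rose by 2.89, Trp53inp1 by 2.75 and Ccng1 by 1.28. Interferon response genes rose in 32 of 36 cases (32 adjusted over the list alone; median 0.97, adjusted p = 6.04e-09, and adjusted p = 0.127 with an estimated correlation), with Oas3 up by 2.75, Ifi44 by 2.88 and Gbp2 by 2.43, and Ifit2 and Eif2ak2 lower (2 adjusted over the list alone; 1 on leaving out any library other than nifedipine 1). Gbp4 had 3 reads in control and 110 with nifedipine, a ratio of 30.5 (95% counting interval 10.2 to 150), and at least 18.5 without cultured control 1, which held all 3. Inflammation and NF-kB genes rose in 10 of 19 cases (10 adjusted over the list alone; median 0.47, adjusted p = 0.00316, and adjusted p = 0.105 with an estimated correlation), led by the endotoxin receptor Tlr4 at 1.62, while its adaptor Myd88 fell by 0.84 (1 adjusted over the list alone). Mitophagy, autophagy and lysosome genes rose in 21 of 33 cases, and Atg3 fell (21 and 1 adjusted over the list alone; median 0.46, adjusted p = 3.79e-05, and adjusted p = 0.117 with an estimated correlation), with Psap up by 0.86 and Pink1 by 1.04. Cytokine receptor and adhesion genes rose in 16 of 24 cases, and Cxcr4 and Itgb1 fell (16 and 2 adjusted over the list alone; median 0.57, adjusted p = 0.00019, and adjusted p = 0.0905 with an estimated correlation), with Csf2rb2 up by 2.19 and Tgfbr2 by 1.04.

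MYC targets and ribosome biogenesis genes fell in 31 of 32 cases and rose in 0 (31 and 0 adjusted over the list alone; median -0.81, adjusted p = 1.86e-14, and adjusted p = 0.0905 with an estimated correlation). Nucleolin (Ncl) fell by 1.29, the spermidine synthase Srm by 1.24 and Npm1 by 1.03, with Myc at 81.3 ± 9.11 and 82.1 ± 11.4 CPM (adjusted p = 0.929). DNA replication genes fell in 38 of 42 cases and rose in 0 (39 and 0 adjusted over the list alone; median -0.62, adjusted p = 7.36e-13), including Mcm3 at -0.82. Mitosis genes fell in 24 of 38 cases (24 adjusted over the list alone; median -0.62, adjusted p = 4.28e-05), including the checkpoint kinase Bub1b at -1.06, while Top2a, Prc1 and Ect2 rose (3 adjusted over the list alone; 5 rises without cultured control 2). The adjusted p was 0.17 for replication and 0.362 for mitosis with an estimated correlation. Of 16 G1 genes, 10 fell (10 adjusted over the list alone; median -0.45, adjusted p = 0.028, and adjusted p = 0.273 with an estimated correlation), among them Cdk6 at -0.74 and cyclin E1 (Ccne1) at -1.37, and the call was lost with features as deposited (0.0567). Ccnd1 rose from 32.9 ± 6.04 to 113 ± 5.56 CPM, Ccnd2 by 0.38 and Mycn by 0.63, the 3 rises of that list (3 adjusted over the list alone).

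Oxidative phosphorylation genes fell in 59 of 78 cases, and Cox7a2l and Atp5s rose (61 and 2 adjusted over the list alone; median -0.48, adjusted p = 2.92e-12). Atp5b fell by 0.79 and cytochrome c (Cycs) by 1.01, and without cultured control 3 there was 1 rise. In the fit corrected for length and GC content 49 fell and 5 rose, with a median of -0.34. Tricarboxylic acid cycle genes fell in 18 of 23 cases and rose in 0 (18 and 0 adjusted over the list alone; median -0.43, adjusted p = 9.14e-06), with Ogdh at -0.80. The adjusted p was 0.17 with an estimated correlation for both lists. Mitochondrial biogenesis and dynamics fell in 24 of 36 cases, and Tfb1m rose (25 and 1 adjusted over the list alone; median -0.34, adjusted p = 9.4e-06, and adjusted p = 0.0905 with an estimated correlation). Hspd1 fell from 837 ± 61.5 to 329 ± 16.7 CPM and Slc25a5 by 0.94. Mcu rose by 0.41 (adjusted p = 0.00912), and Ppargc1a was at 1.20 ± 0.177 and 1.63 ± 0.811 CPM (adjusted p = 0.542).

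Of 10 macrophage markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 1.25, adjusted p = 0.00164, and adjusted p = 0.105 with an estimated correlation). These included Hmox1 and Slc40a1, which also handle heme and iron in other cells, as well as lysozyme (Lyz2) at 1.68 and Apoe at 1.79. Erythroid markers fell in 7 of 11 cases, and Blvrb rose by 1.29 (7 and 1 adjusted over the list alone; median -0.72, adjusted p = 0.0147, and adjusted p = 0.127 with an estimated correlation). The call was lost at 10 CPM (0.235). Gata1, the transcription factor of erythroid and megakaryocytic cells, had 616 reads in control and 2 with nifedipine, a ratio of 371 (95% counting interval 102 to 3070), or at least 185 without nifedipine 3, which held both, Car2 fell by 0.53 and Aqp1 by 1.17.

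The other lists did not pass with nifedipine. Among voltage-gated calcium channel subunits, 1 of 8 rose, Cacnb2 (1 adjusted over the list alone; median 0.53, adjusted p = 0.133). Cacna1c was at 1.35 ± 0.112 and 2.12 ± 0.142 CPM (adjusted p = 0.233), Cacna1d at 0.517 ± 0.144 and 0.696 ± 0.634 CPM (log2 difference 0.42, adjusted p = 0.692), and Cacna1s had 0 reads. The Cacna1d value turned to -0.29 without nifedipine 2 and to -0.22 with limma-voom. Calcium transport and sensing gave 21 rises and 9 falls of 50 (22 and 9 adjusted over the list alone; median 0.19, adjusted p = 0.0937) and passed without cultured control 1 (0.0452). Integrated stress and unfolded protein response genes gave 14 rises and 8 falls of 26 (15 and 8 adjusted over the list alone; median 0.43, adjusted p = 0.0752), and passed without cultured control 3 (0.0477), with no filter (0.0473), with the RPKM read total (0.0390) and in the corrected fit (0.0313). Immediate early genes gave 10 rises of 23 and falls in Hsph1 and Dnajb1 (10 and 2 adjusted over the list alone; median 0.41, adjusted p = 0.0897), and passed at 10 CPM (0.00702) and in the corrected fit (0.0492), with 4 falls without nifedipine 4. Apoptosis regulators gave 8 rises of 21 and 2 falls, Bak1 among them (10 and 2 adjusted over the list alone; median 0.20, adjusted p = 0.0955), with 1 fall without cultured control 1, cultured control 2, nifedipine 1 or nifedipine 2.

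Replication-dependent histones gave 3 rises of 42, in Hist1h1c, Hist1h2bc and Hist1h4c, and 1 fall, in Hist3h2a (2 and 0 adjusted over the list alone; adjusted p = 0.929), with a median of -0.13, a test direction of up, and a median of 0.03 in the corrected fit (5 rises and 0 falls; 3 and 0 with the RPKM read total). Without cultured control 1 there were 4 rises and 3 falls, without cultured control 2 there were 6 and 0 (median 0.35), and without cultured control 3, nifedipine 1, nifedipine 2 or nifedipine 4 there were 0 falls. Glycolysis gave 6 rises and 11 falls of 26 (6 and 12 adjusted over the list alone; median -0.09, mean 0.03, test direction down, adjusted p = 0.17). Fatty acid oxidation gave 7 falls of 25 and rises in Cpt1a, Cpt1c, Acadm and Acot2 (7 and 4 adjusted over the list alone; median -0.06, mean 0.02, test direction down, adjusted p = 0.668), and 6 rises and 6 falls in the corrected fit. Adenosine and nucleotide signalling gave 6 rises of 20 and falls in Ada, Adk, Dpp4, P2rx1 and P2ry1 (6 and 5 adjusted over the list alone; median -0.14, mean 0.09, test direction down, adjusted p = 0.792). Cholesterol synthesis gave 6 rises and 7 falls of 24 (6 and 8 adjusted over the list alone; median -0.10, adjusted p = 0.335), and 3 rises and 9 falls in the corrected fit. Ribosomal proteins gave 12 rises and 13 falls of 81 (11 and 11 adjusted over the list alone; mean -0.02, adjusted p = 0.79), with a median of 0.002 that turned to -0.002 with DESeq2 size factors and to 0.15 in the corrected fit (41 rises and 5 falls, adjusted p = 0.00045). There were 24 rises and 10 falls without nifedipine 2, and 8 and 5 with the RPKM read total.

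Granulocyte and monocyte progenitor markers gave rises in Csf1r, Csf3r, Itgam and Gstm1 and falls in Plac8 and Nkg7 among 10 (4 and 2 adjusted over the list alone; median 0.58, adjusted p = 0.241). Megakaryocyte and platelet markers gave 8 falls of 19 and rises in Selp and F2r (8 and 2 adjusted over the list alone; adjusted p = 0.284), with a median of -0.04 that turned to 0.02 with the RPKM read total. Lymphoid progenitor markers gave 5 rises of 10, Satb1, Notch1, Bcl11a and Lsp1 among them, and a fall in Lck (5 and 1 adjusted over the list alone; median 0.68, adjusted p = 0.241), with 2 falls without nifedipine 4. Endothelial and stromal markers gave a rise in Emcn and a fall in Vwf among 9 (1 and 1 adjusted over the list alone; median -0.04, adjusted p = 0.803), with 0 falls without cultured control 2, nifedipine 1, nifedipine 3 or nifedipine 4. Too few members were measured to test mature neutrophil (0 calls of 1), B cell (0 of 3; 1 rise of 4 without cultured control 2), T and NK cell (Gzmb lower, 1 of 3) and mast cell and basophil markers (Mitf higher, Gzmb and Slc18a2 lower, 3 of 3), with the same counts adjusted over the list alone. Gzmb had 45 reads in control and 0 with nifedipine, at least 18.1-fold lower.

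Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6396 of 12807, of which 3298 were higher and 3098 lower. Changes of 2-fold or more leaned upward, with 933 higher and 261 lower. The libraries of the 2 groups did not overlap for 6559 genes (51.2%, against 5.71% by chance). Exon reads made up 37.3% ± 1.68 of the RPKM read total in control (n = 3) and 36.1% ± 2.90 with nifedipine (n = 4; exact two-sided permutation p = 0.657). Of 31 lists tested, 16 passed with camera's preset correlation, 8 up and 8 down, and 0 with an estimated correlation.

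**Figure D3:**
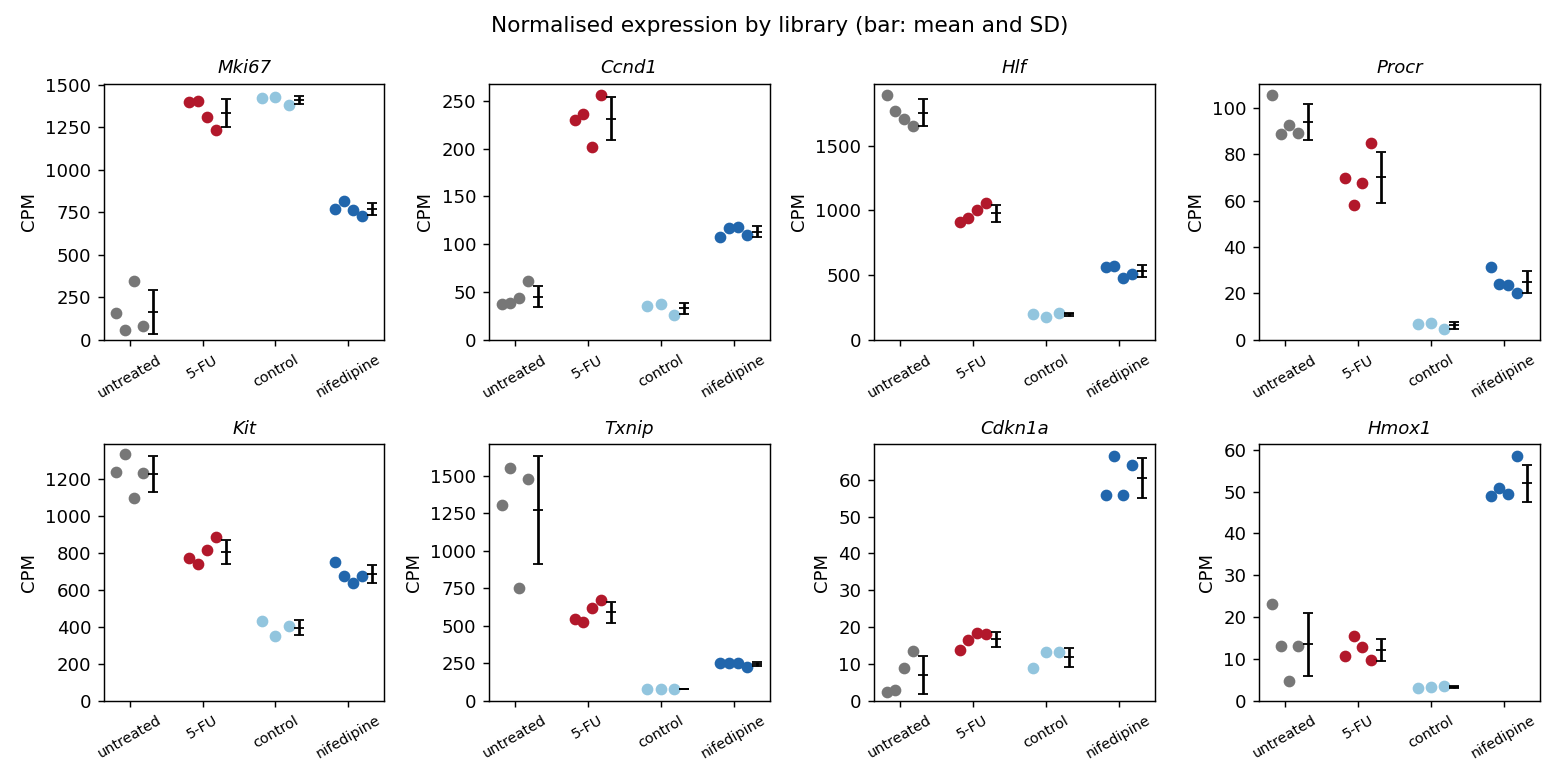
CPM of Mki67, Ccnd1, Hlf, Procr, Kit, Txnip, Cdkn1a and Hmox1 in each library of the 4 groups, with bars for the group mean and SD. Scaling was fitted within each experiment. Hlf averages 1753 and 976 CPM in untreated and 5-FU HSCs and 196 and 529 CPM in cultured control and nifedipine HSCs.

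The last comparison set the nifedipine change against the 5-FU change, to see whether they run together or apart. Genes that 5-FU raised were mostly lower with nifedipine, and genes that 5-FU lowered were mostly higher. Of 3554 5-FU-raised genes tested in culture, 2030 (57.1%) fell with nifedipine against 867.9 expected of independent lists, and 383 (10.8%) rose against 922.5. Of 3023 5-FU-lowered genes, 1533 (50.7%) rose against 784.6 expected, and 166 (5.5%) fell against 738.3. Mki67, Atp5b, Hspd1 and Npm1 rose after 5-FU and fell with nifedipine, whereas Hlf, Procr, Kit, Txnip and Vldlr fell after 5-FU and rose with nifedipine. Ccnd1, Zmat3 and Mcu rose in both comparisons, and Clca3a1 and Itga2b fell in both. Zmat3 and Itga2b after 5-FU, at 2.21 and -1.58, were chosen after their values were seen, as was Clca3a1 at -2.14.

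The 5-FU-raised set had a median log2 fold change of -0.31 with nifedipine (camera p = 3.69e-26, p = 0.00367 with an estimated correlation, fry p = 1.71e-05), and the 5-FU-lowered set a median of 0.35 (camera p = 3.37e-19, p = 0.00121 with an estimated correlation, fry p = 5.24e-06). Other assignments of the cultured libraries gave a camera p as low as 3.21e-24 and 1.73e-18, so its size does not measure the nifedipine effect. Across the 12579 genes tested in both comparisons, Pearson's r was -0.298 (exact two-sided permutation p over 35 assignments of the cultured libraries 0.0286, the smallest they allow) and Spearman's rho was -0.457 (exact permutation p = 0.0571). The correlation is across genes, which are not independent replicates, and r was -0.456 with a filter of 10 CPM. The 2 experiments share no library.

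**Figure D4:**
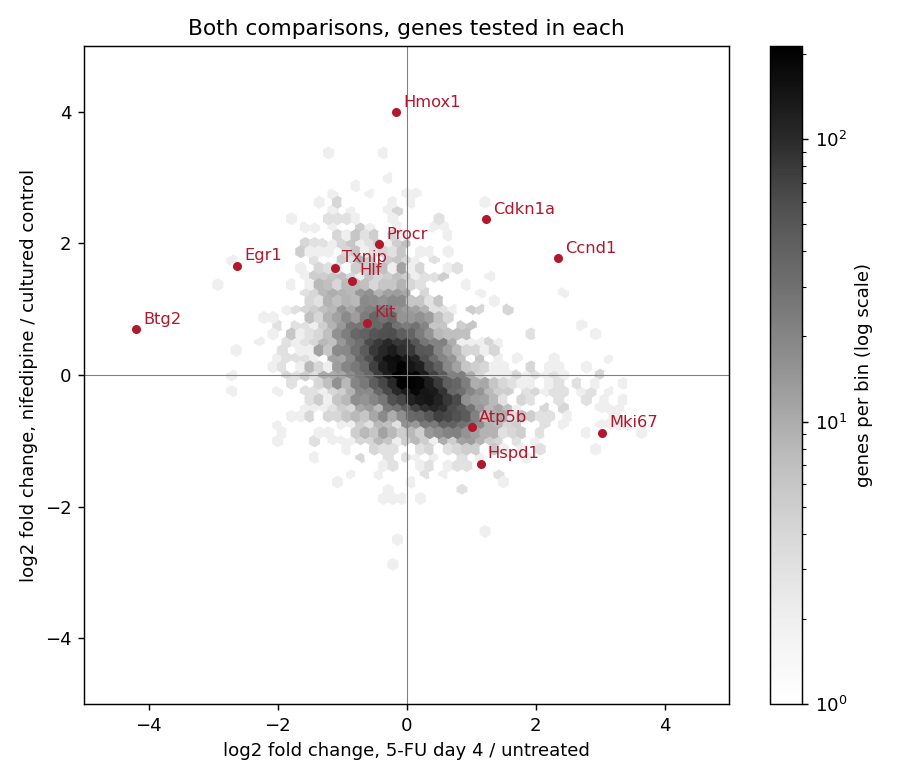
Density of 12557 genes by log2 fold change after 5-FU (x axis) and with nifedipine (y axis), on a logarithmic colour scale, with 12 named genes labelled and 22 genes outside the axes. Mki67, Atp5b and Hspd1 lie at the lower right, and Hlf, Procr, Kit and Txnip at the upper left.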

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

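Chosen only after their results were seen were the depth test of the first pattern and the culture test of the third; the lists of markers for the first pattern were written after the first list was seen and before these tests were run.

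The endothelial and stromal markers averaged 0.85 log2 CPM in untreated 3 and 3.37 in 5-FU 4, apart from the rest of their groups, and the gap of untreated 3 to the nearest other library was 0.903 of the range of its group. Low depth is argued against for untreated 3, since 2 untreated libraries, untreated 2 and 4, had fewer exon reads and higher markers. RNA of stromal cells carried into the sort is a candidate explanation, since 87% of a second list of 23 stromal genes were lowest in untreated 3 and 95.7% were highest in 5-FU 4, where chance gives 25%, and the abundant stromal gene Cxcl12 was at 0.662 CPM in untreated 3 (103 to 1220 in the other untreated libraries) and 290 CPM in 5-FU 4 (0.623 at most in the others). Endothelial RNA stays undecided for both libraries. Of 19 second-list endothelial genes, 78.9% were lowest in untreated 3 and 36.8% were highest in 5-FU 4. By the rule set before the test, the latter share argues against it for 5-FU 4. But that list averaged 3.05 log2 CPM in untreated 3 and 3.01 to 3.83 in 5-FU 1 to 3. The second stromal list averaged 0.94 and 0.74 to 0.86 there. Some endothelial-list genes were thus expressed where stromal genes were low, so the share cannot decide. Tek and Tie1 of that list are also HSC identity genes. On the stromal explanation, carried RNA would sit in the other untreated libraries and in 5-FU 4, so it would differ between the groups. It could then add falls to the 5-FU comparison, and these were not separated from effects of 5-FU. The sort for HSCs should exclude both cell types, and no biological explanation was tested.

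Oxidative phosphorylation genes rose after 5-FU and fell with nifedipine, and they are short. Their medians stood at percentile 100 and 0 among 10000 random lists matched on length and expression, whose medians were 0.396 (middle 95% from 0.255 to 0.539) and -0.215 (-0.357 to -0.102). The random lists hold genes drawn apart from each other, while oxidative phosphorylation genes can vary together. These percentiles may therefore overstate how rare such medians are. In fits corrected for length and GC content the list kept its direction with adjusted p = 6.31e-10 and 6.4e-07 (camera; over all alternatives 1.01e-21 to 0.35 and 1.9e-14 to 0.17, the highest with an estimated correlation), while its median went from 0.74 to 0.40 and from -0.48 to -0.34. This argues against length, GC content and expression as the whole cause, although they may account for part of the size. What the groups themselves differ in stays open, and no biological explanation was tested.

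The nifedipine and 5-FU changes ran against each other. A trend with length, GC content and expression is argued against as the whole cause, with a correlation of -0.245 between residuals. A program of division stays open: the correlation was -0.292 without the 169 genes of the cell cycle and growth lists, but these are too few of 12579 to move it, and other genes of division stay in. The change from untreated to cultured control ran with the 5-FU change. Cultured control minus untreated correlated with 5-FU minus untreated at 0.557 to 0.589 over 6 splits that share no untreated library. Untreated 1, 2 and 4 were high in the endothelial and stromal markers (4.42 to 4.81 log2 CPM). Every split therefore has such a library in both references, and what this adds to the correlation was not separated. Such a correlation across genes does not give the share of the 5-FU change seen in culture. This comparison holds no nifedipine library, and culture and sorting differ between the experiments, so what nifedipine acts on stays open.

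Other splits of the libraries were tried for each result of a model over all genes. As many genes were called in only 1 of 35 splits, the real one, in each comparison. The counts were 6765 after 5-FU (highest other 9) and 6396 with nifedipine (highest other 0). That share is the smallest these splits allow, so they set no tighter bound on chance. Every other split mixes the 2 groups in at least 1 arm, which widens the spread and keeps calls few. For the correlation chance is not excluded: 1 of 35 assignments gave a Pearson's r as large (size 0.298), but the highest other also rounds to 0.298, and Spearman's rho had p = 0.0571. In the exact permutation over these splits the real one alone was as large for the 5-FU-raised genes (1 of 35; camera p = 3.69e-26, lowest other 3.21e-24) and for the 5-FU-lowered genes (1 of 35; p = 3.37e-19, lowest other 1.73e-18). The lowest others come close although those splits called 0 genes, so the size of the camera p is no measure of the nifedipine effect. Chance cannot be excluded for the number of lists called, since 6 of 35 splits gave as many as the 18 after 5-FU (highest other 22) and 7 of 35 as many as the 16 with nifedipine (highest other 18).

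In 417 groups of 4 libraries, the highest or lowest library stood apart by more than the 95% bound of Dixon's ratio (gap over range) in 17, against 20.9 by chance. Besides the markers above, untreated libraries stood apart for Slc16a1 (untreated 2 low, 0.843), Phgdh (untreated 3 high, 0.901), Myc (untreated 4 low, 0.954) and Mcu (untreated 1 high, 0.873). After 5-FU these were the means of inflammation (5-FU 2 low, 0.884), cholesterol synthesis (5-FU 4 high, 0.845) and apoptosis genes (5-FU 2 low, 0.903), Rrm1 (5-FU 4 low, 0.913) and Atp5a1 (5-FU 3 low, 0.855). With nifedipine they were the means of oxidative phosphorylation (nifedipine 2 low, 0.881) and interferon genes (nifedipine 1 high, 0.830), Ugt1a6b (nifedipine 1 low, 0.982), Mfsd2b (nifedipine 1 low, 0.907), Txnip (nifedipine 4 low, 0.876), Gata1 (nifedipine 3 high, 1.00) and Blvrb (nifedipine 3 low, 0.863).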

How the results depend on the processing

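Features as deposited, the RPKM read total, the length and GC correction and the pair of libraries left out together were chosen after seeing the data, as were fry for the 5-FU gene sets and leaving out untreated or 5-FU libraries for the correlation and those sets. Over the settings that change the test, filter or scaling, 6058 (10 CPM) to 7054 (DESeq2) genes were called after 5-FU and 5478 (RPKM read total) to 6582 (limma-voom) with nifedipine. Genes called in both settings kept their direction, except 10 of 5756 in the corrected 5-FU fit. Totals hide lost calls. Of the 6765 calls after 5-FU, 5424 were also made with the RPKM read total and 5756 in the corrected fit. With nifedipine these were 5429 and 5738 of 6396. With a 2-fold minimum, 1572 genes were called after 5-FU (749 higher, 823 lower) and 1194 with nifedipine (933 higher, 261 lower), fewer by construction. With an estimated correlation 0 lists passed in either comparison, where fry called 26 and 24; the estimate counts the correlation of list members within groups. Leaving out 1 library at a time gave 5922 to 6824 genes and 14 to 19 lists after 5-FU, 5638 to 6135 genes and 16 to 17 lists with nifedipine, and, over all 15 libraries, a correlation of -0.300 to -0.281 and p from 1.17e-27 to 1.62e-23 for the 5-FU-raised and 1.7e-20 to 6.43e-18 for the 5-FU-lowered genes. With the replicate number as a block, 6331 and 6283 genes and 18 and 16 lists were called, the correlation was -0.291, and the 5-FU-raised and 5-FU-lowered sets had p = 3.81e-25 and 3.65e-19. Under the block the 5-FU calls of mitophagy (0.0688), integrated stress (0.0569), cytokine receptors (0.0688) and Ccnd2 (0.0670) and the nifedipine call of Cdkn1c (0.0706) were not made, and quiescence (0.0322), B cell (0.0316) and endothelial and stromal markers (0.0403) passed after 5-FU (adjusted p). In the first experiment the numbers gave no sign of pairing. Same-numbered deviations correlated at -0.027, -0.141, 0.101 and 0.163, against -0.453 to 0.384 for other numbers. In the second they correlated at 0.030, 0.048 and 0.012. Each was the highest for its control library but close to none, so pairing there stays undecided. A reversal was counted where a named gene or a list test turned direction and passed before or after. Those were Ccnd2 (0.08) and Fgd5 (0.008) after 5-FU with the RPKM read total, whose construction shifts all genes upward. The ribosomal protein list was reversed in the corrected fits (camera adjusted p = 1.88e-10 and 0.00045, with up to 0.997 and 0.972 over the alternatives). List medians and uncalled genes that turned sign are given above, and the cause was not tested. Of the named genes, over 19 settings after 5-FU 23 results lost and 7 gained a call, and over 17 settings with nifedipine 7 lost and 0 gained. The change of pseudocount was not run. At these depths, group sizes and spreads, 83% and 97% of 2-fold changes but 58% and 77% of 1.5-fold changes were found on simulated data, which did not vary depth.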

Other observations

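The lists of stress genes and their tests were chosen only after the nifedipine changes had been seen, and the criterion for aryl hydrocarbon receptor targets was tightened after its value was seen. With nifedipine, targets of ATF4, the transcription factor of the amino acid and integrated stress response, rose in 15 of 20 cases (16 adjusted over the list alone; median log2 fold change 1.69, camera p = 1.73e-08, p = 0.00654 with an estimated correlation), including Aldh1l2, Trib3, Chac1 and Slc7a3. These 4 large rises prompted the list, so its p partly restates them; without them 11 of 16 rose (median 0.95, camera p = 1.85e-05, p = 0.0365 with an estimated correlation), and the stress list written before the data were examined did not pass (adjusted p = 0.0752). Chaperones of the endoplasmic reticulum fell in 12 of 14 cases (median -0.62, camera p = 1.8e-06, p = 0.115 with an estimated correlation). After 5-FU the chaperones rose in 12 of 14 cases (median 0.69, camera p = 7.21e-06, p = 0.109 with an estimated correlation), and ATF4 targets gave 9 rises and 5 falls of 17. Targets of NRF2, the transcription factor of the oxidative stress response, rose in 15 of 21 cases with nifedipine, and Txn1 and Prdx1 fell. Their median was 0.76 (camera p = 7.22e-06, p = 0.074 with an estimated correlation). After 5-FU they gave 7 rises and 3 falls of 21.

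ATF4 targets rose with nifedipine while 85.7% of the chaperones fell, but the chaperones rose after 5-FU, so their fall may only follow the general reversal between the comparisons, and the route to the ATF4 targets was not tested. A rise of NRF2 targets (71.4% of those measured), Hmox1 among them, is a hypothesis, and Hmox1 also responds to heme. Without Hmox1 14 of 20 rose and 2 fell (camera p = 3.83e-05, p = 0.0848 with an estimated correlation). A rise through the aryl hydrocarbon receptor, which senses many aromatic compounds, stays undecided. Of 7 measured targets 57.1% rose (camera p = 0.0094, p = 0.0441 with an estimated correlation). Without Ugt1a6b, a large rise named above, 3 of 6 rose (camera p = 0.0221, p = 0.0659 with an estimated correlation). Of the 3 targets not shared with other pathways, 0 were called. Direct action of the drug and a response to a change in division, whose rate was not measured here, were not separated.

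In culture, the second lists of endothelial and stromal genes rose with nifedipine in 6 of 11 and 7 of 11 cases (camera p = 0.00346 and 0.0189, p = 0.0279 and 0.057 with an estimated correlation), with 0 and 1 falls. Tie1 and Tek, also HSC identity genes, were among the endothelial rises. Without them 4 of 9 rose, in Egfl7, Adgrl4, Calcrl and Gng11 (camera p = 0.0208, p = 0.0614 with an estimated correlation). Adgrf5, Plpp3, Cd36, Fcgr2b and Tm4sf1 were not called, and the first list of such markers gave 1 rise and 1 fall of 9. Whether other cells were present in the culture was not tested.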
